A study of Homo sapiens with 22 samples.

How the data were processed

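RNA from primary human bronchial and tracheal epithelial cells was measured on 22 HG-U133 Plus 2.0 arrays, 2 of undosed control cells and 2 of cells dosed with each of 10 cigarette smoke condensates. The deposited values are linear intensity values per probe set, made with MAS5 according to the submitters' processing notes. The version of MAS5, its scaling target and its detection calls are not stated. The table held 54675 probe sets and 0 columns that could not be matched to a sample. Groups and replicate numbers follow the sample titles. Nothing in the labels says what a biological replicate was taken from, so the p values measure the spread between these samples.

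The intensities were used as log2(value + 1). The pseudocount was the pooled 10th percentile of all values rounded to a whole number. The 2% trimmed means of the arrays ran from 49.1 to 116.8, a ratio of 2.38. This exceeded the limit of 5% for arrays to count as scaled, so the log2 values were quantile normalised. Of the probe sets, 41097 carried 1 gene symbol, 1801 carried several and 11777 none. The 62 Affymetrix control probe sets, Y-linked genes and XIST were left out of the gene tests. The entrez identifiers of 41043 of the probe sets with 1 symbol were in the RefSeq table, and 0 symbols were updated. Probe sets with a mean log2 value at or above the median of all probe sets, 3.70, were kept, and each gene was represented by its probe set with the highest mean. This gave 11626 genes. The number of arrays limits the precision, and a probe set that reads several related genes, as in the AKR1C, UGT1A and metallothionein families, can carry the signal of its relatives.

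A linear model with 11 group means was fitted with limma 3.58.1 on R 4.3.3, with empirical Bayes moderation of the variance and a trend on mean signal. Replicate number was not a term of this fit and entered only as an alternative. The contrasts were the mean of the 10 condensates against control, each condensate against control, each condensate against the mean of the other 9, and a moderated F test of the differences among the 10 condensates. P values were adjusted by Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. All tests were two-sided except the F tests. Changes are log2 differences with the moderated standard error (SE). The comparisons, gene lists, alternatives and the rule for named genes were chosen before the data were examined. That rule took the 12 genes with the largest rise and the 12 with the largest fall among called genes that changed the same way in all 10 condensates. It also took the 10 genes with the largest range among the condensates, up to 2 risers and 2 fallers for each condensate against the others, and up to 4 members of each list with the smallest adjusted p. Other genes are named where the text says that they were chosen after their values were seen.

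The 24 lists of pathway genes and cell type markers held 647 entries and 635 distinct genes, of which 475 were measured. They were tested on the contrast of all condensates against control with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. List scores were the mean log2 value of a list's genes, each centred on the 20 dosed arrays. Their differences among the 10 condensates were tested by permuting the array labels 100000 times, and 3 relations between scores were tested by permutation across the condensate means, with fewer permutations in the alternatives. RNA quality was read from the GAPDH and ACTB control probe sets and the hybridisation spike-ins, with an exact permutation test over the 231 splits of 2 against 20 arrays, whose smallest possible p is 0.00433. Overlap of the calls was compared with 100 simulated data sets without any effect that shared the control arrays.

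The fit was tested on 10 simulated data sets with 200 changed genes. For all condensates against control it recovered 4.48% of changes of log2 0.5, 42.1% of log2 1 and 81.2% of log2 2, with 4.5 false calls per data set. For CDC5 against control it recovered 1.04%, 17.9% and 68.0%, with 2.3 false calls. For CDC4 against the other condensates it recovered 4.78%, 46.7% and 85.0%, with 4 false calls. Without any effect there were 0.1 false calls per data set, and camera called 0 of 24 random lists. The simulated genes varied independently, without a deviant array or a replicate difference, while the estimated correlation within the mitosis list was 0.67. The simulations therefore do not show the rate of false calls for lists of correlated genes.

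The alternatives were the values as deposited, centring on array medians, pseudocounts of 4 and 16, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, all probe sets, no variance trend, array weights, fits on subsets of the arrays, the replicate number as a block, and leaving out each array in turn. Genome positions were not used here.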

Results

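Gene expression was measured in primary human bronchial and tracheal epithelial cells, the lining cells of the large airways, after 18 h with 1 of 10 cigarette smoke condensates or without any. Condensates, which are the collected particulate matter of smoke, were matched at about 4 µg/ml of nicotine, and 1 µg of total RNA was labelled per array. The series therefore asks what condensates change in airway cells and whether sources differ. Each of the 11 groups, control and CDC1 to CDC10, had 2 arrays. The series title counts 10 sources while the protocol lists 5 commercial and 4 research cigarettes, 9 in all, and the labels do not say which code is which cigarette. Titles of the control arrays carry a prefix that the others lack and whose meaning is not given, so if it marks a separate run, run and dosing cannot be told apart in any comparison with control. The median signal of 21 of the 22 arrays ran from 11.3 to 18.9 intensity units, and 7.07% to 11.6% of their values lay below 1.

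CDC3 replicate 1 stood apart from the other 21 arrays. Its median signal was 6.76, 18.4% of its values lay below 1, and its median Spearman correlation with the others was 0.741, against 0.880 to 0.910 for the rest. The 3' probe set of GAPDH, a glycolytic enzyme used as an RNA quality control, exceeded its 5' probe set by 6.10 on the log2 scale on this array, against -0.08 to 0.06 on the others. For ACTB, the cytoskeletal actin used in the same way, the difference was 7.91, against 0.37 to 0.80. The hybridisation spike-ins bioB, bioC, bioD and cre averaged 11.49 in quantile normalised log2 values, against 10.14 to 10.84. Between dosed and control arrays the mean difference was 0.34 for GAPDH (exact permutation p = 0.225), 0.50 for ACTB (exact permutation p = 0.147) and 0.32 for the spike-ins (exact permutation p = 0.113), for 20 and 2 arrays. For GAPDH and ACTB it rested largely on CDC3 replicate 1. The dosed means, 0.31 and 0.94, exceeded the highest of the other 21 arrays, 0.06 and 0.80. The spike-in difference was 0.27 without CDC3 replicate 1 (exact permutation p = 0.0381), but it rested on 1 control array and was 0.07 without control replicate 1 (exact permutation p = 0.476) and 0.56 without control replicate 2 (exact permutation p = 0.0952). Results are given with all arrays, and again without CDC3 replicate 1 where that changes them.

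**Figure D1:**
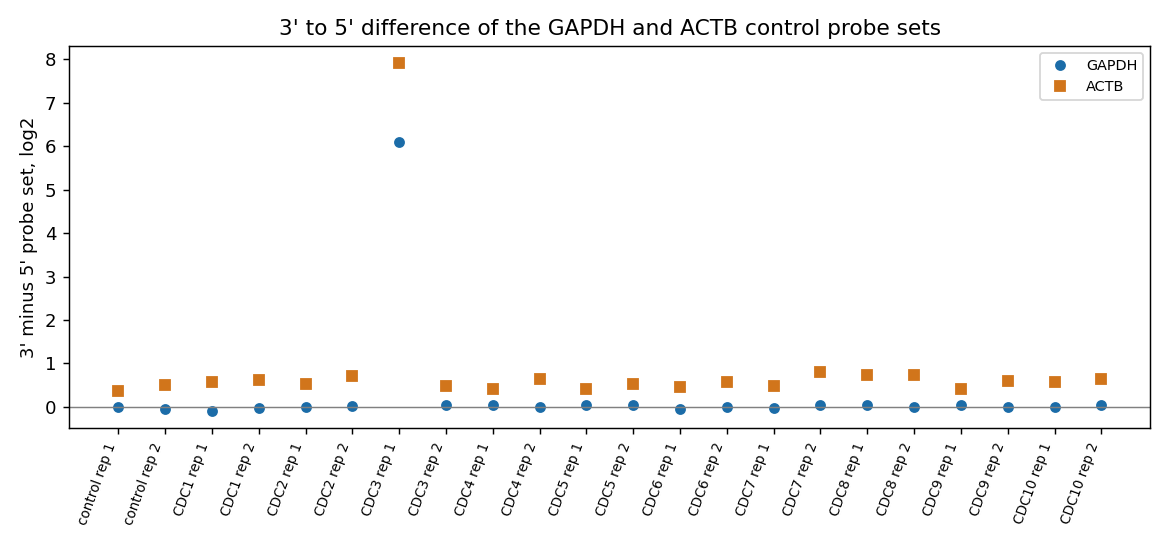
Log2 difference between the 3' and 5' control probe sets of GAPDH and ACTB (vertical axis) on each of the 22 arrays (horizontal axis), 1 point per gene and array. CDC3 replicate 1 lies at 6.10 and 7.91, and the other 21 arrays lie between -0.08 and 0.80.

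Genes higher in dosed cells than in control included several oxidoreductases and the transferrin receptor. TFRC, the transferrin receptor that brings iron into cells, was 4.58-fold higher than in control (log2 change 2.20 ± 0.26 SE, n = 20 and 2 arrays, adjusted p = 0.00245). NQO1, a quinone reductase, was 3.59-fold higher (1.84 ± 0.14, adjusted p = 2.95e-05), and TXNRD1, the cytosolic thioredoxin reductase, was 2.36-fold higher (1.24 ± 0.15, adjusted p = 0.00257). GPAT3, an enzyme of triglyceride synthesis, rose by 1.80 ± 0.32 (adjusted p = 0.0494), NMRAL2P, a transcribed pseudogene, by 1.42 ± 0.19 (adjusted p = 0.00423) and HSD17B2, which inactivates estradiol and testosterone, by 1.28 ± 0.19 (adjusted p = 0.00794). FECH, which inserts iron into heme, rose by 0.90 ± 0.14 (adjusted p = 0.0223). PTGR1, a reductase of prostaglandins and reactive aldehydes, rose by 0.87 ± 0.11 (adjusted p = 0.00291), the iron-binding protein PIR by 0.80 ± 0.12 (adjusted p = 0.0149) and COA6, an assembly factor of cytochrome c oxidase, by 0.73 ± 0.13 (adjusted p = 0.0494). These 10 genes were higher than control in all 10 condensates.

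Limma called 14 genes up and 0 down of 11626, with 508 at an unadjusted p under 0.05. Of the 14, 7 rose by log2 1 or more. The other called genes were AKR1C1, AKR1C2, AKR1C3 and GCLM, which were not above control in CDC5. Without any scaling between arrays the median gene was -0.34 below control on the log2 scale, against -0.01 here, and only NQO1 was called (1.57, adjusted p = 0.00168). Replacing each gene's probe set by the mean of its probe sets ended the call of NQO1 (1.49, adjusted p = 0.124) and TFRC (1.82, adjusted p = 0.0661), and 6 genes were called. The count was 3 without control replicate 1, 5 without control replicate 2, 62 without CDC3 replicate 1 (53 up and 9 down) and 530 without CDC3 replicate 2 (171 up and 359 down, so falls became the larger part). Without control replicate 1, TFRC (adjusted p = 0.129), NMRAL2P (0.129), HSD17B2 (0.231), PTGR1 (0.102), PIR (0.263), FECH (0.942), AKR1C1 (0.108), AKR1C3 (0.166) and GCLM (0.836) missed the threshold. Without control replicate 2, TXNRD1 (adjusted p = 0.187), NMRAL2P (0.190), HSD17B2 (0.218), PTGR1 (0.187), PIR (0.435), FECH (0.156), AKR1C1 (0.155), AKR1C3 (0.138) and GCLM (0.489) missed it. FECH also missed it narrowly, at adjusted p values up to 0.0537, without CDC1 replicate 1, CDC5 replicate 2, either CDC8 array, CDC9 replicate 1 or CDC10 replicate 1. GPAT3 stayed past the threshold only without CDC1 replicate 2 or any 1 of the CDC3 and CDC4 arrays, with adjusted p values up to 0.851 elsewhere, and COA6 and GCLM only without either CDC3 array, with values up to 1.00 elsewhere.

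**Figure D2:**
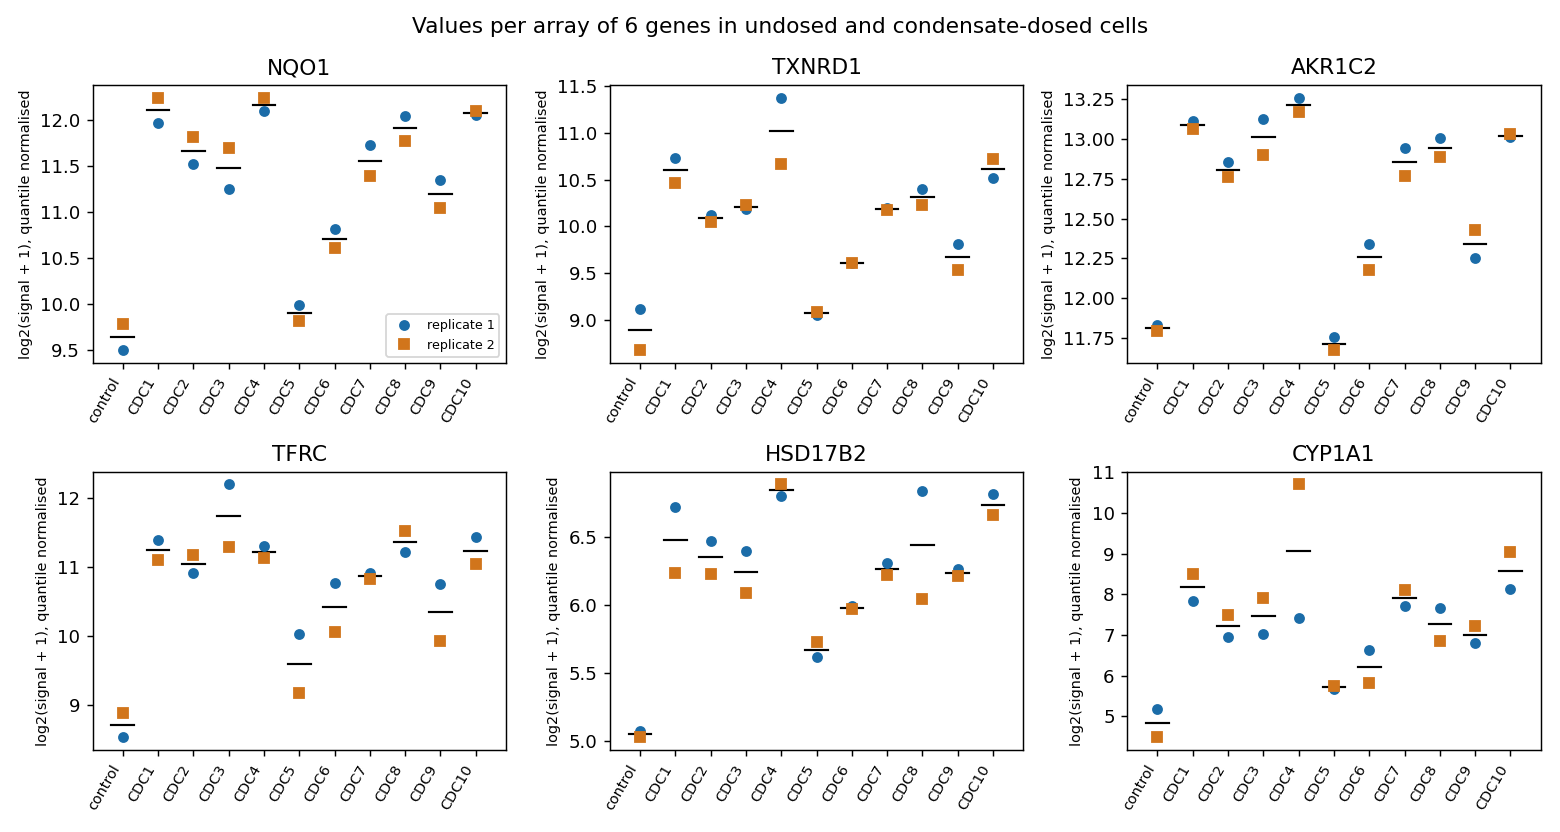
Quantile normalised log2(signal + 1) of 6 genes (vertical axes) in control cells and in each of 10 condensates (horizontal axes), with 1 point per array and a bar at the mean of both. NQO1, TXNRD1, TFRC, HSD17B2 and CYP1A1 have all 10 condensate means above control, while AKR1C2 in CDC5 does not.

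Leaving out CDC3 replicate 1 brought CYP1A1 and CYP1B1 past the threshold. These cytochromes, which oxidise polycyclic aromatic hydrocarbons, rose by 2.67 ± 0.51 (adjusted p = 0.0224) and 2.13 ± 0.41 (adjusted p = 0.0232) over 19 dosed and 2 control arrays. With all arrays they stood at 2.63 (adjusted p = 0.137) and 2.09 (adjusted p = 0.173), and array weights, which keep every array, also brought both past it (adjusted p = 6.19e-04 and 0.00253). GPX2, an epithelial glutathione peroxidase, rose by 1.97 ± 0.14 (adjusted p = 7.34e-07), and ALDH3A1, an aldehyde dehydrogenase, by 1.38 ± 0.23 (adjusted p = 0.0104). TRMT2A, a tRNA methyltransferase, rose by 1.94, the cell adhesion gene NRCAM by 1.54 and SAMD5 by 1.28. Of the other genes taken by the same rule, TFRC, NQO1, GPAT3, NMRAL2P and HSD17B2 rose again. In this comparison 9 genes fell. TNC, the matrix glycoprotein tenascin C, fell by 0.91 ± 0.15 (adjusted p = 0.0104), the intermediate filament gene VIM by 0.85 ± 0.15 (adjusted p = 0.0109), FBN2, a fibrillin, by 0.55 ± 0.08 (adjusted p = 0.00298) and COL7A1, the collagen of anchoring fibrils, by 0.41 (adjusted p = 0.0454). NTM fell by 0.88, STON2 by 0.64, MBNL2 by 0.60, AHNAK2 by 0.46 and GPX1, the widespread glutathione peroxidase, by 0.35. The count of rises was 53.

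Targets of NRF2, the transcription factor of the oxidant response, rose together. Of 38 measured targets 36 were higher and 2 lower than control, with a mean of 0.67. Of these, 7 were called over all genes and 20 when adjusted over the list alone, all upward. The list passed camera (adjusted p = 2.05e-33) and held with an estimated correlation (adjusted p = 1.32e-04) and with fry (adjusted p = 9.68e-05). AKR1C2 (0.91 ± 0.08, adjusted p = 1.48e-04) and AKR1C1 (0.68 ± 0.08, adjusted p = 0.00257), which reduce steroids and carbonyls, were among them, although their probe sets may read each other's transcripts. Without CDC3 replicate 1, 19 targets were called over all genes and 30 adjusted over the list alone. Targets of AhR, the receptor for aromatic hydrocarbons, were higher in 8 of 12 and lower in 4, with a mean of 0.57. None of them was called over all genes and 4 were called up adjusted over the list alone, the leading members being CYP1A1, TIPARP (0.53 ± 0.11, adjusted p = 0.155), which ADP-ribosylates AhR, CYP1B1 and ALDH1A3 (0.61 ± 0.15, adjusted p = 0.325), a retinaldehyde dehydrogenase. This list passed camera (adjusted p = 1.21e-04) but had adjusted p = 0.119 with an estimated correlation. Without CDC3 replicate 1, 5 members were called up over all genes, and 5 up and 2 down adjusted over the list alone. TIPARP (adjusted p = 0.00705) and ALDH1A3 (0.00779) also passed with array weights.

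Cell cycle genes split. All 32 mitosis genes were lower, with a mean of -0.35 and camera adjusted p = 9.04e-08, but adjusted p = 0.411 with an estimated correlation. Members with the smallest p were DLGAP5 (-0.47 ± 0.20), CENPF (-0.64 ± 0.31), NEK2 (-0.57 ± 0.28) and KIF20A (-0.56 ± 0.28), all of the spindle or kinetochore. Of 33 DNA replication genes 25 were higher and 8 lower, with a mean of 0.22, camera adjusted p = 1.21e-04 and adjusted p = 0.411 with an estimated correlation. As deposited, its mean was -0.10, still above the median gene at -0.34. FEN1 (0.93 ± 0.28), which trims replication flaps, and the helicase factors MCM6 (0.64 ± 0.23) and MCM10 (0.77 ± 0.31) led this list. In both lists 0 genes were called by limma over all genes and 0 adjusted over the list alone, but 2 DNA replication genes were called up over the list alone when CDC3 replicate 1 was left out. A fit with replicate number as a block and without that array was chosen after the data were seen. In it FEN1 and MCM6 passed upward and CENPF and NEK2 downward over all genes, while DLGAP5, KIF20A and MCM10 did not pass.

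Extracellular matrix genes and matrix proteases were lower as a group. Of 29 measured, 25 were lower and 4 higher, with a mean of -0.24. The list passed camera (adjusted p = 5.35e-05), held with an estimated correlation (adjusted p = 0.0147) and with fry (adjusted p = 0.0270), and had 0 members called over all genes and 1 called down adjusted over the list alone. With CDC3 replicate 1 left out, 2 were called down over all genes, and 6 down and 1 up over the list alone. TNC stood at -0.93 ± 0.17 (adjusted p = 0.0535), the gelatinase MMP9 at -1.23 ± 0.36, SPARC at -0.57 ± 0.18 and TGFBI at -0.44 ± 0.17. Over the 13 alternatives other than leaving out each array in turn, limma called TNC down in 5, SPARC in 2 and TGFBI in 0. MMP9 was called in 1 of 12. Fibroblast markers were lower in 9 of 10 and higher in 1, with a mean of -0.41, camera adjusted p = 0.00340 and adjusted p = 0.119 with an estimated correlation. They included VIM (-0.98 ± 0.38), the collagens COL5A2 (-0.82 ± 0.33) and COL1A1 (-0.92 ± 0.46), and MMP2 (-0.37 ± 0.19), and 0 were called by limma, over all genes or adjusted over the list alone, against 1 and 4 called down when CDC3 replicate 1 was left out. Without the filter on low signal their mean was 0.02 (adjusted p = 0.455). Over the same 13 alternatives limma called VIM down in 3, COL5A2 in 1, COL1A1 in 1 and MMP2 in 0. Cultured airway epithelial cells also express VIM and several matrix genes.

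ATF4 targets of the integrated stress response were lower in 27 of 33 and higher in 6, with a mean of -0.24, camera adjusted p = 0.00483, adjusted p = 0.505 with an estimated correlation and 0.263 as deposited. Their leading members went both ways, with JDP2 at -0.74 ± 0.23, NUPR1 at -1.0 ± 0.48, SLC1A4 at -0.37 ± 0.19 and the cystine transporter SLC7A11, also a target of NRF2, at 0.55 ± 0.22. Squamous differentiation genes were lower in 21 of 27 and higher in 6, with a mean of -0.30, camera adjusted p = 0.0160 and adjusted p = 0.505 with an estimated correlation. The list missed the threshold as deposited (adjusted p = 0.278), with the filter at the 75th percentile (0.0578), without control replicate 2 (0.268) and without CDC3 replicate 2 (0.0864). IVL, a protein of the cornified envelope, stood at -0.67 ± 0.34, SPRR2B at -0.55 ± 0.36, CALML3 at -0.31 ± 0.24 and SCEL at -0.23 ± 0.18. Basal cell markers were lower in 13 of 15 and higher in 2, with a mean of -0.26, camera adjusted p = 0.0269 and adjusted p = 0.411 with an estimated correlation. This list missed it as deposited (adjusted p = 0.175), with centring on array medians (0.130) and without control replicate 1 (0.137). DST (-0.44 ± 0.17) and ITGA6 (-0.72 ± 0.57), parts of hemidesmosomes, and PDPN (-0.52 ± 0.24) and CDH3 (-0.44 ± 0.27) had the smallest p. In these 3 lists 0 genes were called by limma over all genes and 0 adjusted over the list alone, but 2 basal cell markers were called down over the list alone when CDC3 replicate 1 was left out. Of the 9 lists past the threshold with the preset correlation, only the NRF2 and matrix lists held with an estimated correlation.

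The other 15 lists did not pass camera. Cytokines and NF-kB targets were higher in 12 of 23 and lower in 11 (mean 0.13, adjusted p = 0.305), and 1 of them, the interleukin IL1B (1.04 ± 0.25), was called adjusted over the list alone. Without CDC3 replicate 1, IL1B rose by 1.10 ± 0.14 (adjusted p = 7.20e-04), and 4 members were called up over the list alone. The chemokines CXCL1 (0.82 ± 0.25) and CXCL8 (1.23 ± 0.43) and IL1A (0.65 ± 0.31) did not pass. Over the 13 alternatives other than leaving out each array in turn, limma called CXCL8 in 1 (adjusted p = 0.0115). It called IL1A in 2 (adjusted p down to 0.0237) and CXCL1 in 0. The cytokine list passed as deposited (adjusted p = 0.0196) and with the filter at the 75th percentile (0.00617). As deposited, where the median gene lay at -0.34, the means of 4 lists of higher genes fell below 0, to -0.21 for cytokines, -0.11 for hypoxia, -0.22 for heat shock and -0.17 for cholesterol, all above the median gene. Glycolysis and hypoxia genes had a mean of 0.17 but a median of -0.03 (11 of 25 higher and 14 lower, adjusted p = 0.0811, 1 called adjusted over the list alone), with EGLN3, an oxygen-sensing hydroxylase, at 1.78 ± 0.46, PFKFB3 at 1.04 ± 0.44, ANKRD37 at 0.95 ± 0.35 and PFKFB4 at 0.58 ± 0.20. The hypoxia list passed as deposited (adjusted p = 4.61e-04), with centring on array medians (0.00984), and without control replicate 2 (0.0450), CDC1 replicate 1 (0.0498) or CDC3 replicate 1 (0.0351), where 16 genes were higher and 9 lower with a median of 0.04. Without CDC3 replicate 1 its camera adjusted p was 0.338 with an estimated correlation. The value of EGLN3 came from a probe set with a mean log2 signal of 3.92, close to the filter on low signal. The other EGLN3 probe set, with a mean of 3.75, stood at -0.19 (limma unadjusted p = 0.778). The rise of EGLN3 therefore rested on 1 probe set. Over the alternatives other than leaving out each array in turn, it ran from 0.71 to 1.85. UDP-glucuronosyltransferases and glutathione transferases were higher in 8 of 16 and lower in 8 (mean 0.05, -0.27 as deposited and 0.11 without CDC3 replicate 1, adjusted p = 0.357, 1 called adjusted over the list alone), including the microsomal transferase MGST1 (0.32 ± 0.08), NAT1 (0.60 ± 0.31), UGT1A6 (0.39 ± 0.29) and GSTM2 (-0.35 ± 0.30), and with CDC3 replicate 1 left out 1 was called up over all genes and 3 over the list alone.

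In the remaining lists 0 genes were called by limma, over all genes or adjusted over the list alone, but when CDC3 replicate 1 was left out 2 interferon-stimulated genes were called down and 1 autophagy and lysosome gene up over the list alone. ER chaperones were higher in 18 of 27 and lower in 9 (mean 0.02, -0.28 as deposited and 0.06 without CDC3 replicate 1, adjusted p = 0.357), with CRELD2 at 0.50 ± 0.25, SEC61B at 0.33 ± 0.19 and ERN1 at -0.66 ± 0.38. Heat shock genes were higher in 13 of 19 and lower in 6 (mean 0.07, adjusted p = 0.0846), with the co-chaperones DNAJA1 at 0.84 ± 0.34 and HSPH1 at 0.33 ± 0.21, and this list passed as deposited (0.00565), with the filter at the 75th percentile (0.0462) and without CDC3 replicate 1 (0.0237, mean 0.14). In that last comparison its camera adjusted p was 0.338 with an estimated correlation. Cholesterol synthesis genes were higher in 15 of 22 and lower in 7 (mean 0.13, adjusted p = 0.0596), with NSDHL at 0.49 ± 0.20, INSIG1 at 0.51 ± 0.25, HMGCS1 at 0.56 ± 0.41 and IDI1 at 0.38 ± 0.29. That list passed as deposited (adjusted p = 0.0111), with centring on array medians (0.0286), with the filter at the 75th percentile (0.0462), without CDC3 replicate 1 (0.0298, but 0.606 with an estimated correlation), and without replicate 2 of CDC2 (0.0467), CDC5 (0.0332), CDC6 (0.0456), CDC7 (0.0406), CDC9 (0.0356) or CDC10 (0.0381). Metallothioneins and zinc export genes were lower in 7 of 8 and higher in 1 (mean -0.16, adjusted p = 0.0596), with MT1F at -0.28 ± 0.17, MT1E at -0.18 ± 0.12, MT1H at -0.26 ± 0.28 and the zinc exporter SLC30A1 at -0.29 ± 0.22, and they passed without CDC4 replicate 1 (0.0279). Interferon-stimulated genes were lower in 16 of 20 and higher in 4 (mean -0.21, adjusted p = 0.0596), with EPSTI1 at -0.80 ± 0.27, IFIT1 at -0.67 ± 0.47, OAS1 at 0.54 ± 0.28 and USP18 at 0.48 ± 0.27. They passed with centring on array medians (adjusted p = 0.0177), without control replicate 2 (0.00593), and without replicate 1 of CDC1 (0.0498), CDC3 (0.0298, but 0.434 with an estimated correlation), CDC5 (0.0465), CDC6 (0.0328), CDC7 (0.0435) or CDC10 (0.0332). Targets of p53 were lower in 14 of 23 and higher in 9 (mean -0.06, -0.03 without CDC3 replicate 1, adjusted p = 0.434), with the DNA repair genes XPC at -0.35 ± 0.16 and DDB2 at -0.47 ± 0.39 and AEN at 0.63 ± 0.28. Autophagy and lysosome genes were lower in 19 of 26 and higher in 7 (mean -0.05, adjusted p = 0.309), but lower in 14 and higher in 12 without CDC3 replicate 1 (mean 0.01, adjusted p = 0.711), with CTSB at -0.21 ± 0.11, NPC2 at -0.18 ± 0.11, CTSL at 0.38 ± 0.24 and GLA at 0.54 ± 0.38. Ribosomal protein genes were lower in 19 of 21 and higher in 2 (mean -0.10, -0.02 without CDC3 replicate 1, adjusted p = 0.234), and passed without CDC3 replicate 2 (1.38e-04). With centring on array medians their mean was 0.02.

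Markers of other cell types were sparse. Of the listed markers, 13 of secretory cells were measured (5 higher and 8 lower, mean -0.08, adjusted p = 0.642), 6 of ciliated cells (2 and 4, mean -0.13, adjusted p = 0.267), 4 of endothelial cells (1 and 3, mean -0.26, adjusted p = 0.252) and 2 of leukocytes (0 and 2, mean -0.66, adjusted p = 0.0596). Secretory genes included CLCA2 (-0.43 ± 0.29), TFF3 (0.76 ± 0.60) and SLPI (-0.48 ± 0.52). Ciliated genes included TUBA1A (-0.35 ± 0.20), RFX3 (-0.36 ± 0.36) and RFX2 (-0.35 ± 0.35). PECAM1 stood at -0.50 ± 0.35 and EGFL7 at -0.46 ± 0.54 among endothelial markers, and LAPTM5 at -0.54 ± 0.30 and CORO1A at -0.77 ± 0.72 among leukocyte markers. The leukocyte list passed with centring on array medians (adjusted p = 0.0325) and without replicate 1 of CDC1 (0.0433), CDC2 (0.0420), CDC6 (0.0412) or CDC10 (0.0466).

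**Figure D3:**
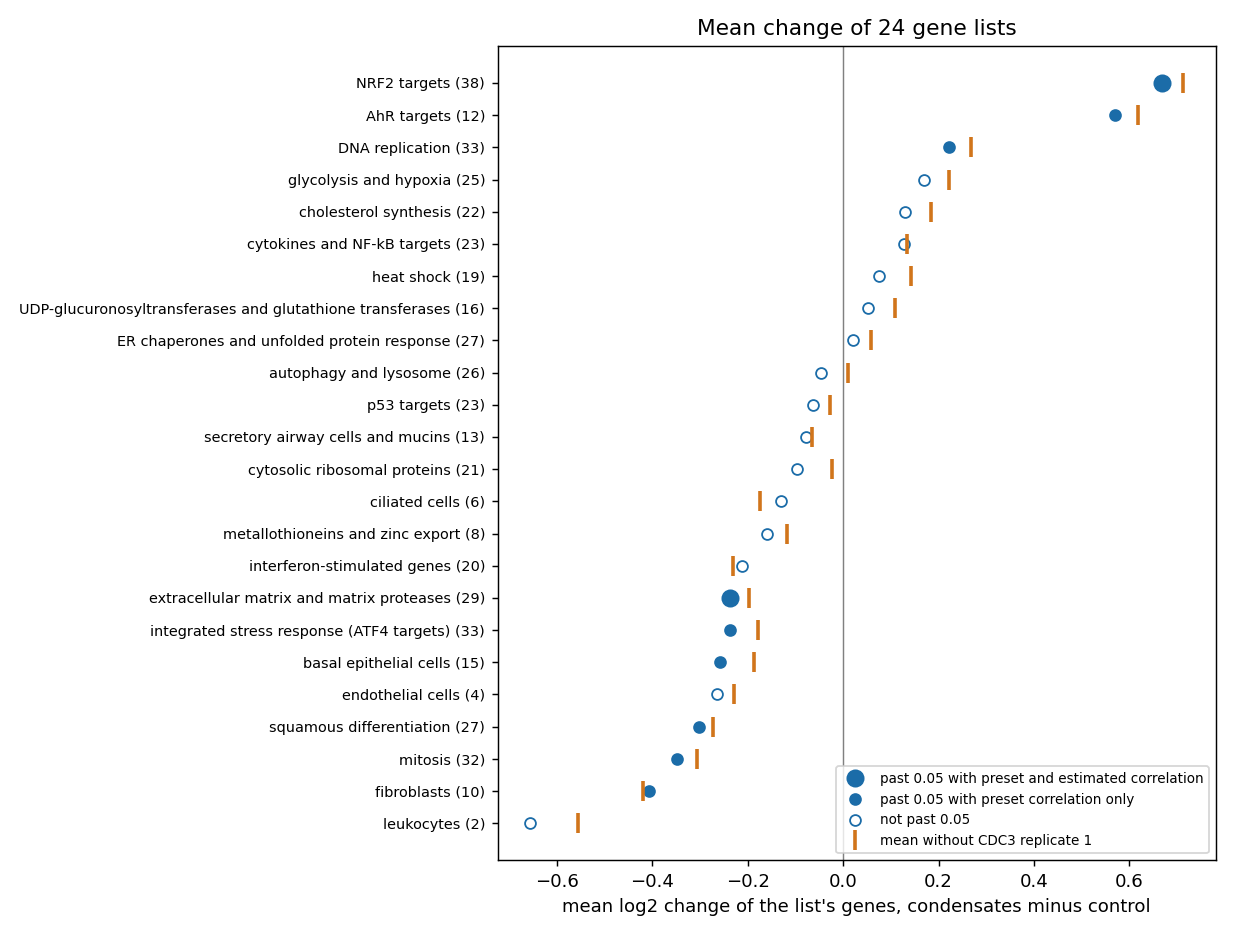
Mean log2 change of the measured genes of each of 24 lists, condensates minus control (horizontal axis), with the number of genes measured in brackets and an orange tick at the mean without CDC3 replicate 1. NRF2 targets (0.67) and AhR targets (0.57) have the highest means, and large filled points mark the lists that pass with both correlations.

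CDC4 had the most genes called against control over all arrays. Limma called 22 up and 8 down, including CYP1A1 (4.24, but 2.61 without CDC4 replicate 2) and GPX2 (2.98), and among the falls the spindle gene DLGAP5 (-1.43), NTM (-1.77) and FBN2 (-0.81). For CDC10, 14 rose and 3 fell, with NQO1 (2.44), TFRC (2.53) and HSD17B2 (1.69) up and TNC (-1.32) and FBN2 (-0.79) down. For CDC1, 15 rose and 0 fell, led by TFRC (2.53), NQO1 (2.47) and NMRAL2P (2.02). For CDC3, 12 rose, led by TFRC (3.03) and GPAT3 (2.66), and 2 fell, SIX5 (-2.87) and FBN2 (-0.83), which were chosen after their values were seen. For CDC7 and CDC8, 7 rose in each and 0 fell, NQO1 rising by 1.93 and 2.27. For CDC2, 4 rose, named after their values were seen, TFRC (2.33), NQO1 (2.03), AKR1C2 (0.99) and AKR1C1 (0.75), and for CDC9, NQO1 alone rose (1.56, adjusted p = 0.0108). Limma called 0 genes for CDC5, with 179 at an unadjusted p under 0.05, and 0 for CDC6, with 136.

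These counts moved with single arrays. For CDC1 the count of 15 became 7 without control replicate 1, 5 without control replicate 2, 9 without CDC1 replicate 1 and 63 without either CDC3 array. For CDC2 the count of 4 became 1 without either control array or CDC2 replicate 1, 2 without CDC2 replicate 2 or any 1 array of CDC1, CDC7, CDC8 or CDC10, and 21 without either CDC3 array. For CDC3 the count of 14 became 5 and 7 without control replicates 1 and 2, 9 without any 1 array of CDC7 or CDC10, and 7001 without CDC3 replicate 2. For CDC4 the count of 30 became 8 and 10 without control replicates 1 and 2, 128 without CDC4 replicate 2 (32 up and 96 down), 222 without CDC3 replicate 1 (99 up and 123 down) and 232 without CDC3 replicate 2 (101 up and 131 down), so falls became the larger part. As deposited 15 genes rose and 2315 fell. For CDC7 the count of 7 became 1 without CDC7 replicate 1, 26 without either CDC3 array, and 2 without CDC7 replicate 2 or any 1 array of the control, CDC1, CDC2, CDC6, CDC8, CDC9 or CDC10. For CDC8 the count of 7 became 2 and 3 without control replicates 1 and 2, 2 and 4 without CDC8 replicates 1 and 2, and 35 without either CDC3 array. For CDC9 the call of NQO1 was lost without either control or CDC9 array, and the count was 4 without either CDC3 array. For CDC10 the count of 17 became 5 and 4 without control replicates 1 and 2, 6 and 4 without CDC10 replicates 1 and 2, 11 without any 1 array of CDC1 or CDC2, and 62 and 61 without CDC3 replicates 1 and 2. For CDC6 the count was 1 without either CDC3 array, and with CDC3 replicate 1 left out this gene, named after its value was seen, was NQO1 (1.07, adjusted p = 0.0489). For CDC5 it stayed at 0 without each of the 22 arrays. Of the genes named per condensate, those called without either control array were NQO1 in CDC1, CDC2, CDC7, CDC8 and CDC10 and TFRC in CDC3, and NMRAL2P in CDC1 was called without control replicate 1. Without either array of the condensate itself, GPX2 and FBN2 in CDC4, TFRC, HSD17B2, TNC and FBN2 in CDC10 and TFRC and AKR1C1 in CDC2 lost their calls. DLGAP5 lost its call without CDC4 replicate 1, TFRC in CDC1 without CDC1 replicate 1, AKR1C2 in CDC2 without CDC2 replicate 1, and GPAT3, SIX5 and FBN2 in CDC3 without CDC3 replicate 1. Arrays of other condensates ended calls of GPX2 and DLGAP5 in CDC4, TNC and FBN2 in CDC10, GPAT3, SIX5 and FBN2 in CDC3 and TFRC and AKR1C1 in CDC2, at adjusted p values up to 0.0928.

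A few genes recurred across condensates. NQO1 was called up in 8 of the 10 comparisons with control, AKR1C1, AKR1C2 and TFRC in 7, and AKR1C3 and TXNRD1 in 6. These 6 genes passed in at least 5 comparisons and 18 genes in at least 2, where independent lists would give 1.8e-10 and 0.242. No gene could be called in all 10, because CDC5 and CDC6 had 0 called genes. The 100 simulated data sets without any effect gave means of 0 and 0.07, but they had only 0.61 genes called in any comparison, against 34 observed, so they say nothing about recurrence or the shared controls. Part of the excess may come from the shared controls, since all 10 comparisons use the same 2 control arrays, which are too few to be split between them. The 6 genes became 2 without either control array, either CDC8 array or CDC10 replicate 2, 3 without CDC10 replicate 1, 21 without CDC3 replicate 1 and 30 without CDC3 replicate 2.

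Few genes differed among the condensates. Limma's F test called 9 genes, with 320 at an unadjusted p under 0.05, and 7 of the 9 are on the NRF2 list. All 9 were lowest in CDC5 and highest in CDC4. NMRAL2P spanned 2.56 on the log2 scale (adjusted p = 0.0190), NQO1 2.27 (adjusted p = 8.55e-04), AKR1C3 2.01 (adjusted p = 0.00227) and TXNRD1 1.95 (adjusted p = 0.0167). GCLM and GCLC, the subunits of the enzyme that starts glutathione synthesis, spanned 1.81 (adjusted p = 0.0177) and 1.34 (adjusted p = 0.0190). PTGR1 spanned 1.61 (adjusted p = 0.00185), AKR1C2 1.5 (adjusted p = 3.91e-04) and AKR1C1 1.16 (adjusted p = 0.00516). The count became 5 without CDC1 replicate 1, CDC5 replicate 2 or either CDC6 array, 4 without CDC5 replicate 1, 34 without CDC3 replicate 1 and 4964 without CDC3 replicate 2. NQO1, AKR1C2, AKR1C3 and PTGR1 passed without each of the 22 arrays, AKR1C1 without all but CDC5 replicate 1 (adjusted p = 0.142) and TXNRD1 without all but CDC1 replicate 1 and the CDC5 and CDC6 arrays (adjusted p up to 0.176). NMRAL2P and GCLM passed without 10 of the 22 arrays (adjusted p up to 0.186 and 0.176) and GCLC without 6 (adjusted p up to 0.371). With centring on array medians only NQO1 of the 9 still passed, and AKR1C2 and AKR1C3 stood at adjusted p = 0.163 and PTGR1 at 0.0518. With the mean of each gene's probe sets only AKR1C3 of the 9 still passed, and NQO1 stood at adjusted p = 0.873, AKR1C2 at 0.958 and PTGR1 at 0.566. As deposited PTGR1 missed the threshold as well (adjusted p = 0.137).

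CDC4 had the strongest and CDC5 the weakest expression of these genes. In CDC4 against the other 9 condensates, limma called 6 genes up and 6 down. NMRAL2P was 1.31 ± 0.19 higher and SRXN1, which repairs oxidised peroxiredoxins, 1.26 ± 0.19 higher (both adjusted p = 0.0164). KIAA1549L was lower (-1.83 ± 0.31, adjusted p = 0.0382), as was RUNX2, a transcription factor of bone formation (-1.55 ± 0.25, adjusted p = 0.0207). In CDC5, 11 genes were called down and 0 up, and NQO1 (-1.75 ± 0.14, adjusted p = 3.13e-05) and NMRAL2P (-1.54 ± 0.19, adjusted p = 0.00197) fell furthest. For CDC4 the count of 12 became 325 without CDC3 replicate 1 (94 up and the rest down), 1748 without CDC3 replicate 2 (923 up and 825 down), 138 without CDC4 replicate 2 (10 up and 128 down) and 1664 as deposited (3 up and 1661 down), and for CDC5 the count of 11 became 43, 480 and, without CDC5 replicate 1, 4. NMRAL2P missed the threshold for CDC4 without either CDC4 array (adjusted p = 0.0654 and 0.0584) and for CDC5 without CDC5 replicate 1 (adjusted p = 0.188). SRXN1 missed it without CDC4 replicate 1 (adjusted p = 0.179) and RUNX2 without CDC4 replicate 2 (adjusted p = 0.112). KIAA1549L stood at -0.94 without CDC4 replicate 1 and passed only without either CDC3 array or CDC4 replicate 2, with adjusted p values up to 0.263 elsewhere. With array weights NMRAL2P (adjusted p = 0.117), RUNX2 (0.0950) and KIAA1549L (0.136) missed it for CDC4, as did NMRAL2P as deposited (0.80, adjusted p = 0.0522) and KIAA1549L with no filter (adjusted p = 0.0712).

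For CDC3 against the other condensates limma called 630 genes up and 1451 down, and this count rested on replicate 1. As deposited 2 rose and 4768 fell. PPDPF (2.18 ± 0.46) and PRMT1 (-4.43 ± 1.29), an arginine methyltransferase, had adjusted p = 0.0454, as had EIF3G (-4.27 ± 1.21), a translation factor, and ADAMTS10 (1.79 ± 0.59) had adjusted p = 0.0499. Without CDC3 replicate 1 the count was 3, and TMEM158 (-3.18), the growth factor FGF2 (-3.12) and PKIB (-2.83), named after their values were seen, were lower in the remaining array. PRMT1 then stood at 0.20, EIF3G at 0.07 and PPDPF at 0.60, and none of the 4 genes passed. Without CDC3 replicate 2 the count was 7780, without any 1 of the other 20 arrays it was 0 to 3, and the 4 genes passed only without CDC3 replicate 2, with adjusted p values up to 1.00 elsewhere.

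The remaining 7 condensates were not set apart from the others over all arrays, but some of them were when CDC3 replicate 1 was left out. Limma called 0 genes for CDC1, CDC2, CDC6, CDC7, CDC8, CDC9 and CDC10, with 182, 100, 152, 88, 112, 96 and 113 at an unadjusted p under 0.05. Without CDC3 replicate 1, the NRF2 targets GPX2 (0.91), GCLM (0.49), AKR1C2 (0.41) and GCLC (0.41) and PTGR1 (0.59) rose in CDC1, and GPX2 (-0.90), NQO1 (-0.88), GCLM (-0.66), AKR1C2 (-0.50) and PTGR1 (-0.57) fell in CDC6. In CDC10, GCLM (0.61) and PTGR1 (0.54) then rose and VWA1 (-2.21) fell. These genes were named after their values were seen. Without CDC3 replicate 2 the 7 counts were 366, 210, 227, 167, 309, 228 and 319, and leaving out an array of the condensate itself gave 2 for CDC1 replicate 2 and 1 for CDC6 replicate 1, either CDC7 array and CDC8 replicate 2.

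Scores of the 24 lists were compared among condensates over the 20 dosed arrays. The NRF2 score was lowest in CDC5 (-0.66) and highest in CDC4 (0.60), with a pooled SD within condensates of 0.22, an F ratio of 7.28, a permutation p of 0.00331 and an adjusted p of 0.0794. The mitosis score ran the other way, from -0.82 in CDC4 to 0.36 in CDC5 (permutation p = 0.216, adjusted p = 0.818). With the permutation test 0 lists passed over all arrays, and 1 was under an unadjusted p of 0.05. Without CDC3 replicate 1 the NRF2 score differed among condensates (F ratio 129, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 2.40e-04), from -0.70 in CDC5 to 0.55 in CDC4. The ribosomal protein score then also passed (adjusted p = 0.0314), over a range of -0.04 to 0.04. Without CDC3 replicate 2, 7 lists passed.

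Condensates with higher NRF2 scores had higher AhR and lower mitosis scores. Over all arrays, neither the AhR nor the mitosis score passed the test of differences among condensates (permutation p = 0.391 and 0.216). Across the 10 condensate means the NRF2 and AhR scores correlated with r = 0.966 (permutation p = 1e-05, the smallest possible, adjusted over 3 relations 3.0e-05) and rho = 0.952 (permutation p = 1.1e-04, adjusted 3.3e-04), and r was 0.962 without CDC5 and CDC3, the 2 farthest from the median. Within replicate 1 arrays r was 0.836 (permutation p = 0.00110; 0.759 without CDC3), and within replicate 2 arrays 0.922 (permutation p = 1.7e-04). NRF2 and mitosis scores correlated with r = -0.807 (permutation p = 0.00119, adjusted 0.00178) and rho = -0.818 (permutation p = 0.00555, adjusted 0.00832), and r was -0.745 without CDC5 and CDC4. Within replicate 1 arrays r was -0.642 (permutation p = 0.0406; -0.875 without CDC3), and within replicate 2 arrays -0.750 (permutation p = 0.00642). This relation was not seen in the values as deposited (r = -0.0147, adjusted p = 0.969) or without CDC3 replicate 2 (r = -0.457, adjusted p = 0.185). NRF2 and ATF4 scores, whose lists share SLC7A11, did not correlate (r = 0.435, permutation p = 0.212, adjusted 0.212; rho = 0.309, permutation p = 0.388, adjusted 0.388; r = 0.205 without CDC5 and CDC4). They went opposite ways within replicate 1 arrays (r = 0.815, permutation p = 0.00151) and replicate 2 arrays (r = -0.503, permutation p = 0.134), and passed without CDC3 replicate 2 (r = 0.645, adjusted p = 0.0454) or CDC5 replicate 2 (r = 0.638, adjusted p = 0.0487).

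**Figure D4:**
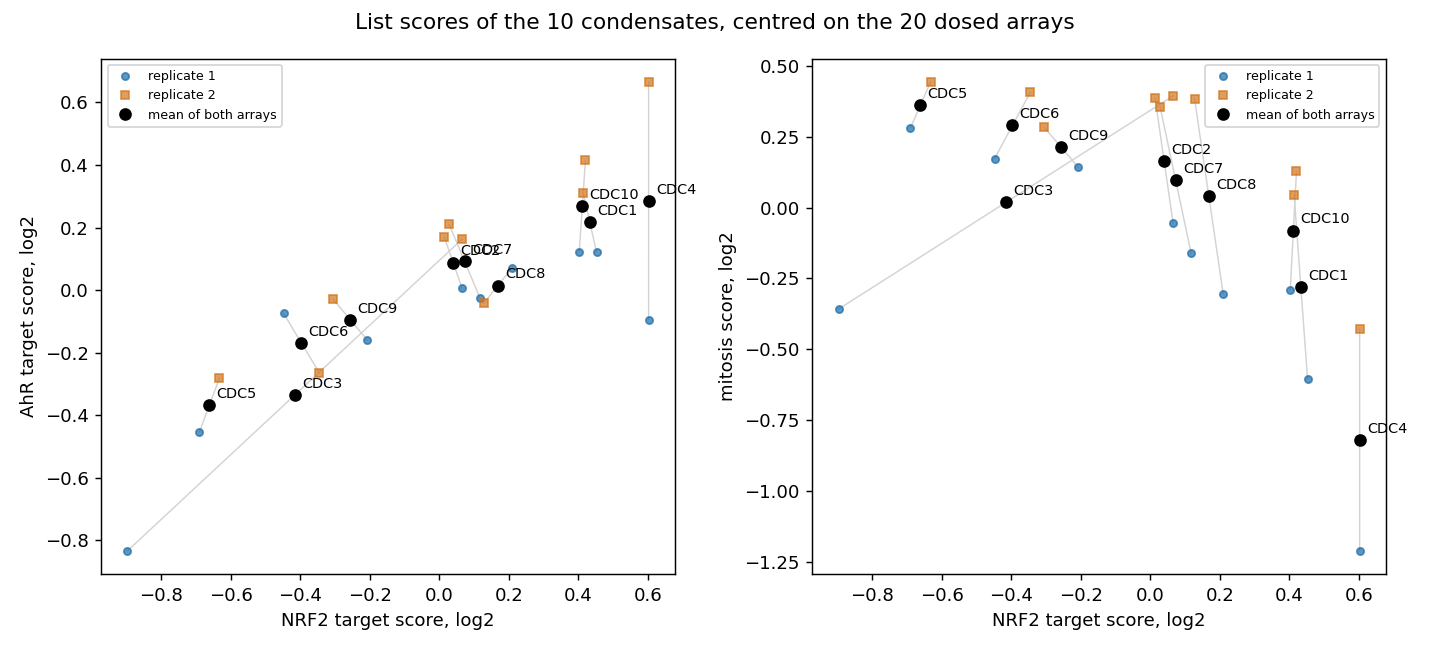
List scores of the 10 condensates on the log2 scale, NRF2 targets (horizontal axes) against AhR targets (left) and mitosis genes (right), with 1 small point per array joined by a line to the black mean of both arrays. CDC5 has the lowest NRF2 mean (-0.66) and CDC4 the highest (0.60), and the AhR and NRF2 means correlate with r = 0.966.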

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

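Of the tests in this part, those of brightness in CDC3 replicate 1, of a mix-up with undosed cells, of an evenly weaker exposure, and of poorer RNA and a uniformly stronger response in CDC4 were chosen only after the result was seen.

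The condensates differed from each other in 9 genes by the F test, and each difference is given here as the range of the condensate means on the log2 scale. The ranges were 2.563 for NMRAL2P, 2.268 for NQO1, 2.01 for AKR1C3, 1.946 for TXNRD1, 1.814 for GCLM, 1.612 for PTGR1, 1.496 for AKR1C2, 1.344 for GCLC and 1.156 for AKR1C1. Against the other condensates, 2081 genes differed in CDC3, 12 in CDC4 and 11 in CDC5. These differences were found by tests between groups. In data outside the gene table, 1 of the 4773 probe sets without a single gene name was higher in dosed than in control cells among 27257 probe sets tested.

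CDC3 replicate 1 stood apart from the other 21 arrays, and without it 3 genes in place of 2081 differed between CDC3 and the other condensates. Low brightness alone is argued against by the 2907 brightest genes. Over them the median rank correlation of this array with the others was 0.5586, against 0.894 to 0.960 for the rest. The 3' minus 5' difference of the bioB spike-in, -0.142, lay within -0.27 to 0.12. This argues only against a hybridisation failure that strikes the 2 ends differently. A failure that moves both ends alike would leave the difference unchanged and stays open. The mean spike-in level of 11.49 lay above the 10.14 to 10.84 of the others. It was read after quantile normalisation, which shifts the values of a dim array, so it does not decide how the hybridisation went. An effect of the condensate is argued against by replicate 2. Its median signed deviation over the 2081 genes was 0.04745 of that of replicate 1, although 74.8% of them lay on the same side. RNA that was broken, or copied only at its 3' end, stays open, because GAPDH and ACTB had a 3' minus middle difference above every other array (6.32 and 6.31, against at most 0.26 and 0.39), although the middle of GAPDH lay below its 5' end by 0.23 and not between the ends. This technical explanation may account for most of the CDC3 genes, as a hypothesis found and tested on the same array.

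CDC5 had the lowest NRF2 scores of the 10 condensates. Scaling of the arrays is argued against, since at least 0.9507 of the difference from the other condensates was left as deposited and with centring on array medians. For leading genes the CDC5 change was 0.45 of that of the others outside the NRF2 list and -0.02 inside it. The difference was 0.475 (permutation p = 0.00540 over genes, which are not independent replicates). This does not settle an evenly weaker exposure, because the list was singled out for being low in CDC5 on these same arrays. A dose response that bends differently for the 2 sets would also give such a difference. A mix-up of a CDC5 array with undosed cells cannot be told apart from a weak response, because the smaller of the CDC5 arrays' changes outside the NRF2 list was 0.3758 of that of the others (the other array 0.527), between what a mix-up and a full response would give. A difference between the sources, which the design names, stays open as a hypothesis and was not tested itself.

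CDC4 stood apart with the highest NRF2 scores and the lowest mitosis scores. Over the other 17 dosed arrays without CDC3 replicate 1 the NRF2 score did not follow the trimmed mean signal (r = 0.01226, permutation p = 0.963, rho = -0.0613, permutation p = 0.817, and r = -0.151 without the 2 farthest arrays). The CDC4 arrays, at 60.6 and 59.7, were dimmer than all of these, which ran from 68.1 to 116.8. The test therefore does not reach the brightness of CDC4 and did not cover the mitosis score, so dim arrays stay open. Poorer RNA is argued against by ACTB, whose 3' minus 5' difference was at most 0.6375 in CDC4, within 0.37 to 0.80 on the others. A uniformly stronger response cannot be told apart, because of the genes picked against 1 set of the other condensates 62.68% changed the same way in the remaining ones against control (50.0% and 66.6% for the 2 ways of picking), between what was set for and against it, although their median change of 0.08 lay below the 1.34 that a response 1.56 times as strong would give. A difference between the sources, which the design names, stays open as a hypothesis and was not tested itself.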

How the results depend on the processing

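The pseudocount of 16, the removal of both CDC3 arrays, and the replicate block with CDC3 replicate 1 left out were chosen only after the data were seen. Pseudocounts of 1 (the same as the one used) and 4 and the filter at the 75th percentile left every count of called genes, lists and scores within 1.5 times its value. Of the results for named genes under all alternatives, 3751 kept their direction and their side of the threshold, 156 passed it newly, 295 no longer passed and 4 reversed. Of those for lists, 770 kept their side of the threshold, 45 passed newly, 23 no longer passed and 0 counted as reversed. A list that changed direction without passing in either fit, as ribosomal proteins did by their mean with centring on array medians, was counted among the 770. PRMT1 reversed to 0.195 without CDC3 replicate 1 and 0.316 with the replicate block added, and EIF3G to 0.0749 and 0.163, while without CDC3 replicate 2 they stood at -9.06 and -8.63 (all for CDC3 against the other condensates). Unless a reason is given, the cause was not tested. MAS5 signal includes background, so differences in weakly expressed genes are limited by it, and with 2 control arrays each control value weighs on every comparison with control.

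With values as deposited, the median gene of the comparison of all condensates with control lay at -0.34 and not at -0.01, and 1 gene was called. Against control there was 1 in CDC1, 1 in CDC2, 5112 in CDC3 (5100 of them down), 2330 in CDC4 (2315 down), 0 in CDC7, 3 in CDC8, 0 in CDC9 and 5 in CDC10. Against the other condensates, CDC3 had 4770 (4768 down), CDC4 1664 (1661 down) and CDC5 7. The F test called 3, 1 gene was called in at least 5 of the 10 comparisons with control, counted as shared, and the NRF2 and mitosis scores correlated with r = -0.0147.

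With each array centred on its median, 6 genes were called for all condensates, 5 for CDC1, 1 for CDC2, 5 for CDC3, 12 for CDC4, 1 for CDC7, 1 for CDC8 and 6 for CDC10 against control. CDC5 had 7 against the others, the F test called 1, 1 list score differed and 1 gene was shared. With the mean of the gene's probe sets the counts against control were 6 for all condensates, 9 for CDC1, 0 for CDC2 and CDC3, 18 for CDC4, 0 for CDC7, CDC8 and CDC9, and 7 for CDC10. CDC5 had 7 against the others, the F test called 1, and 0 genes were shared.

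With no filter, CDC7 had 2 and CDC10 had 10 against control, and CDC3 had 0 against the others. With no trend of the variance, CDC2 had 1, CDC7 1, CDC8 3, CDC9 0 and CDC10 11 against control, CDC3 had 2 against the others, and the F test called 4. The pseudocount of 16 gave 1 list score. Camera with an estimated correlation called 2 lists, and fry in place of camera called 2.

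With array weights, 144 genes were called for all condensates (96 up and 48 down), 109 for CDC1, 46 for CDC2, 0 for CDC3, 70 for CDC4, 3 for CDC6, 37 for CDC7, 197 for CDC8, 17 for CDC9 and 164 for CDC10 against control. Against the others there were 0 in CDC3, 5 in CDC4, 39 in CDC5, 3 in CDC6 and 1 in CDC10, and the F test called 30. With only the condensate's and the control arrays, limma called 71 for CDC1, 45 for CDC2, 0 for CDC3, 15 for CDC4, 1 for CDC6, 28 for CDC7, 359 for CDC8, 7 for CDC9 and 103 for CDC10, from 4 arrays each.

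With a replicate block, 22 genes were called for all condensates (19 up and 3 down), 38 for CDC3, 86 for CDC4 (39 up and 47 down) and 12 for CDC8 against control, 88 for CDC4 against the others (18 up and 70 down), and 11 genes were shared. TNC (adjusted p = 0.0152) and FBN2 (0.0402) then passed downward and CYP1B1 (0.00436) and ALDH1A3 (0.0386) upward. The difference between replicates 1 and 2 correlated between 2 groups with a median of 0.155 over 55 pairs of groups (-0.137 to 0.358), and without CDC3 all 45 pairs lay above 0, 34 of them above 0.1. With CDC3 replicate 1 left out, replicate 1 lay above replicate 2 on the first principal component in all 10 groups with both arrays. The fit and the score tests behind the results left replicate number out. Their p values therefore count this shared difference as spread within groups and ignore any pairing. With CDC3 replicate 1 left out of the replicate block fit, the counts against control were 313 for all condensates (190 up and 123 down), 226 for CDC1, 62 for CDC2, 81 for CDC3, 760 for CDC4, 5 for CDC6, 54 for CDC7, 266 for CDC8, 13 for CDC9 and 195 for CDC10. Of the genes named for the lists, 21 passed in this fit but not with the array left out alone. They were FEN1 (adjusted p = 0.0212), MCM6 (0.0167), CRELD2, DNAJA1, IL1A, EGLN3, PFKFB4, ANKRD37, GLA and NAT1 upward, and CENPF (0.0230), NEK2 (0.0358), JDP2, NUPR1, DST, CDH3, ITGA6, COL5A2, COL1A1, MMP9 and SPARC downward. For EGLN3 the probe set not used stood at -0.19 for all condensates against control in the fit with all arrays. Against the others the counts were 16 for CDC1, 3 for CDC3, 801 for CDC4, 73 for CDC5, 11 for CDC6, 3 for CDC9 and 10 for CDC10. The F test called 133, 3 list scores differed, 69 genes were shared, and the hybridisation spike-ins passed with 0.271.

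With both CDC3 arrays left out, 63 genes were called for all condensates, 63 for CDC1, 21 for CDC2, 223 for CDC4, 1 for CDC6, 26 for CDC7, 35 for CDC8, 4 for CDC9 and 61 for CDC10 against control. Against the others there were 7 in CDC1, 309 in CDC4, 43 in CDC5, 5 in CDC6 and 4 in CDC10. The F test called 38, 14 lists passed, 2 list scores differed, 21 genes were shared, and the spike-ins passed with 0.266. No value for CDC3 exists under this alternative.

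Leaving out each array in turn, the count ran from 3 to 530 for all condensates against control. Against control it ran from 5 to 63 for CDC1, 1 to 21 for CDC2, 5 to 7001 for CDC3, 8 to 232 for CDC4, 0 to 1 for CDC6, 1 to 26 for CDC7, 2 to 35 for CDC8, 0 to 4 for CDC9 and 4 to 62 for CDC10. Against the others it ran from 0 to 366 for CDC1, 0 to 210 for CDC2, 0 to 7780 for CDC3, 10 to 1748 for CDC4, 4 to 480 for CDC5, 0 to 227 for CDC6, 0 to 167 for CDC7, 0 to 309 for CDC8, 0 to 228 for CDC9 and 0 to 319 for CDC10. The F test called 4 to 4964, list scores numbered 0 to 7, and shared genes 2 to 30. The correlation of the NRF2 and ATF4 scores ran from 0.109 to 0.645, that of the NRF2 and mitosis scores from -0.864 to -0.457, and the spike-in difference from 0.0700 to 0.564. The highest F count came without CDC3 replicate 2, where by construction the deviant replicate 1 adds nothing to the spread within groups. A lone array is assumed to vary like the other groups.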

Other observations

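The tests of the 3 gene lists, and the probe sets and the gene SGK1 given after them, were chosen only after the data were seen. Proteasome subunits, the parts of the complex that degrades proteins, were higher in 22 of 27 with a mean of 0.16 (camera adjusted p = 3.53e-05, adjusted p = 0.0956 with an estimated correlation), and without CDC3 replicate 1 in 26 of 27 with a mean of 0.20 (camera adjusted p = 1.33e-07). In that comparison PSMA3 rose by 0.40 ± 0.08 (adjusted p = 0.0462) and the list had adjusted p = 0.149 with an estimated correlation. Targets of the glucocorticoid receptor were lower in 11 of 11 with a mean of -0.48 (camera adjusted p = 8.55e-06, adjusted p = 0.0121 with an estimated correlation), and without CDC3 replicate 1 the mean was -0.47 (adjusted p = 5.51e-05 and 0.0277). The leucine zipper gene TSC22D3 stood at -1.03, the cell cycle inhibitor CDKN1C at -1.01 and the clock gene PER2 at -0.60, and 0 of the 11 passed alone by limma. Of the 11 genes, 1 is also in a list of the report.

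Genes of iron handling and heme synthesis were higher in 9 of 14 with a mean of 0.37. TFRC and FECH, whose calls prompted the list, carried much of this, and the other 12 averaged 0.18 (7 higher and 5 lower). The 10 that are also not on the NRF2 list averaged 0.08 (5 higher and 5 lower). With CDC3 replicate 1 left out, 11 of 14 were higher with a mean of 0.38, the 12 averaged 0.19 (9 higher), the 10 averaged 0.09 (7 higher), and FTL, the light chain of the iron store ferritin, also rose (0.42 ± 0.05, adjusted p = 2.11e-04). ALAS1, the first enzyme of heme synthesis, stood at 0.42 and the heme-degrading HMOX1 at 1.04, and neither passed. The NRF2 list holds 2 of the 14 genes. All values are log2 differences of the condensates from control.

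Among probe sets without a single gene name, 9 were higher and 2 lower in dosed cells when CDC3 replicate 1 was left out. In the comparison of CDC5 with the other condensates without that array, SGK1, a kinase gene induced by glucocorticoids, was 0.91 higher (adjusted p = 0.00315).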
